A study of Homo sapiens with 19 samples.

How the data were processed

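Gene-level tables of 3 experiments were analysed: short reads of HCT116 (DMSO, GSK025 and GSK715, n = 3 each), short reads of WiDr (DMSO and GSK715, n = 3 each) and ONT full-length cDNA of WiDr (DMSO and GSK715, n = 2 each), all after 96 h. Per the labels, the short-read libraries were poly(A)-enriched and sequenced as pairs on a NovaSeq, and the ONT libraries on a PromethION. The authors name cutadapt, HISAT2, StringTie, DESeq2, minimap2 and Salmon and the build GRCh38, without versions or the step each was used for, and the annotation release and the strand of the libraries are not stated. The deposited short-read tables hold raw counts per gene, all of them whole numbers. The deposited ONT table holds estimated counts per gene, of which 15.1% are not whole, and they were rounded before the fit. A deposited table of ONT read statistics gives reads and lengths in bases per library and, per the file headers, the share of full-length reads in percent: 82.7% and 83.8% with DMSO, 84.8% and 84.0% with GSK715. In the ONT libraries the estimated counts summed to 36.5% to 38.5% of the full-length reads.

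Samples were grouped by the label of line, method and compound. In both WiDr tables the columns named NC were taken as DMSO by elimination, since DMSO is the only control group the labels give. Ensembl gene IDs were joined to symbols with a gene name table and GENCODE 29, which also gave coordinates and exonic overlaps: 60612 IDs for HCT116, 63086 for WiDr and 82890 for ONT. The ONT table includes 3991 IDs that are not from Ensembl, with 8.49% to 9.81% of the counts per library. They stayed in the fit and are not named. The tables of the lines share 60259 IDs, and those of WiDr share 61975. Library totals were 64.6 to 66.9 M counts in HCT116, 59.6 to 82.4 M in WiDr and 1.45 to 1.67 M in ONT, so weak genes are measured less precisely in the last. Nothing states that the replicates of a group were separate cultures, so p-values measure the spread between these libraries, whether biological or technical. Within groups, no library was a copy of another by the counting spread of their differences.

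Each comparison was fitted in R 4.3.3 with edgeR 4.0.16: filterByExpr (minimum count 10, minimum total 15), TMM scaling, estimated dispersions and the quasi-likelihood F-test, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Genes changed at least 2-fold were counted as well. The comparisons were GSK025 with DMSO, GSK715 with DMSO and GSK715 with GSK025 in HCT116, GSK715 with DMSO in WiDr short reads and in WiDr ONT, and the interactions between lines and between read types. The last answer whether a response differs, and each was fitted over the IDs shared by its tables. Sets of genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. The 24 lists were the PRMT family, methionine and SAM metabolism, DNA damage and growth arrest genes such as CDKN1A and MDM2, interferon-stimulated genes, MHC class I antigen presentation, DNA replication, mitosis, homologous recombination and Fanconi genes, Wnt targets, colonocyte, goblet and enteroendocrine markers, SR and hnRNP proteins, the snRNP core, cleavage and polyadenylation factors, the ATF4 response, endoplasmic reticulum chaperones, sterol synthesis, ribosome biogenesis, NF-kB and mesenchymal genes, markers of stromal, endothelial and immune cells, mitochondrially encoded genes and replication-dependent histones. The groups, comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. Members of a list that had a group without counts were set against a floor of 3 counts over the group, which left the medians of the lists that passed equal to 2 decimals, except that of sterol synthesis genes between the read types (-0.56, and -0.53 at the floor).

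Genes were named by rule: the 6 largest increases and 6 largest decreases among called genes with a symbol, a mean of at least 5 CPM and all replicates of one group on the same side of the other (4 and 4 for ONT and for the interactions), the 2 called members of each list with the smallest adjusted p in each direction, and PRMT1 and PRMT5 throughout. The text prints a part of these, and some genes that the rule takes are not reported here. Genes that share at least 10% of exonic bases (set after seeing the data) with another gene, readthrough genes, pseudogenes and near-identical families are called uncertain. Smaller overlaps, as of PRMT1, are not. The expected correlation of fold changes that share DMSO libraries was tested on simulated data of 20 unchanged sets. Alternatives were RLE size factors, library totals without a composition factor, no count filter, the Wald test of DESeq2 1.42.0, the replicate number as a block, each replicate left out in turn, glmTreat against a 1.5-fold change, no mitochondrially encoded genes, only the groups compared in the fit, and for correlations a prior count of 2 and a minimum of 5 CPM. Chosen after seeing the data were short reads thinned to the mean ONT total and the ONT table without IDs from outside Ensembl. Where a left-out replicate leaves an ONT group with 1 library, that library is assumed to vary like the other group. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

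The pipeline was tested on simulated data in which 200 genes were changed by 1.5-, 2- or 4-fold and 1 list by 1.5-fold among otherwise unchanged counts. Of the planted changes that passed the count filter, 43.9%, 60.6% and 71.0% were recovered for GSK025 in HCT116, 39.1%, 46.9% and 70.8% for GSK715 in HCT116, 42.9%, 60.0% and 75.0% between the inhibitors, 46.3%, 64.1% and 76.6% in WiDr, 20.3%, 62.3% and 91.9% in ONT, 34.3%, 50.8% and 48.3% between the lines and 1.54%, 18.8% and 31.7% between the read types. In the short-read comparisons most misses lay under 5 CPM, while in ONT no planted gene did. False calls made up 3.50%, 7.91%, 8.97%, 6.79%, 2.50%, 7.02% and 0% of the calls in the same order, no call had the wrong sign, and the planted list was found in each. Other lists were called in 1, 1, 2, 0, 0, 1 and 0 cases. Transcript isoforms, splicing and read-level properties were not analysed here.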

Results

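RNA was sequenced in 19 libraries of HCT116 and WiDr, which are human colorectal carcinoma cell lines, after 96 h with an inhibitor of protein arginine methyltransferases (PRMTs) or with the solvent DMSO. These enzymes methylate arginine side chains, many of them in RNA-binding proteins. GSK025 (GSK3235025, given at 10 µM) inhibits PRMT5, the main enzyme of symmetric dimethylation, and GSK715 (GSK3368715, 5 µM) inhibits the type I enzymes, of which PRMT1 is the most abundant. HCT116 was sequenced with short paired-end reads in 3 groups (DMSO, GSK025 and GSK715, n = 3 each), and WiDr in 2 groups (DMSO and GSK715, n = 3 each). Full-length cDNA of WiDr was also read on an Oxford Nanopore (ONT) sequencer (DMSO and GSK715, n = 2 each). Library totals (M is 1e6) are given with the processing. Levels are TMM-scaled CPM (mean ± SD), and changes log2 fold changes (log2FC) with an approximate standard error (SE). Interactions have their own dispersion, so their SE can be below a line's. Genes said to rise, fall or differ passed an adjusted p of 0.05. Lists with no second count gave the same numbers adjusted alone.

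The inhibitors act on the enzymes as proteins and leave open what happens to their mRNAs. In HCT116, PRMT1 (ENSG00000126457, GRCh38 chromosome 19, 49675786 to 49689029) rose from 233 ± 7.94 CPM with DMSO to 312 ± 15.4 CPM with GSK025 (log2FC 0.42, SE 0.047, adjusted p = 9.1e-06) and to 317 ± 14.4 CPM with GSK715 (log2FC 0.45, SE 0.047, adjusted p = 4.7e-06). PRMT5 (ENSG00000100462, GRCh38 chromosome 14, 22920511 to 22929585) rose from 145 ± 3.71 to 259 ± 7.90 CPM with GSK025 (log2FC 0.84, SE 0.043, adjusted p = 1.6e-08) and to 170.2 ± 7.23 CPM with GSK715 (log2FC 0.23, SE 0.043, adjusted p = 0.00064). The GSK715 call of PRMT5 ended with library totals in place of TMM scaling (adjusted p = 0.182). Between the inhibitors, PRMT5 was lower with GSK715 (log2FC -0.61, SE 0.043, adjusted p = 1.6e-07), whereas PRMT1 did not pass (log2FC 0.025, SE 0.047, adjusted p = 0.708). In WiDr, GSK715 lowered PRMT5 from 74.1 ± 0.827 to 51.9 ± 1.24 CPM (log2FC -0.51, SE 0.034, adjusted p = 4.6e-07). PRMT1 went from 312 ± 1.67 to 287 ± 4.56 CPM (log2FC -0.12, SE 0.026, adjusted p = 0.0027), a small decrease that did not hold with library totals (log2FC 0.0071). Neither passed in the ONT libraries (PRMT1 log2FC -0.089, SE 0.12, adjusted p = 0.732, PRMT5 log2FC -0.12, SE 0.26, adjusted p = 0.857). Exons of PRMT5 overlap an antisense gene in part, and the strand of the reads is not stated, so its level is uncertain. So are those of ASNS, ATR, CCDC92, CCND1, CEACAM5, DDIT3, DDIT4, DUSP6, HLA-B, ICAM1, IFITM1, IRF2BPL, LRP11, LYZ, MAT2A, PABPN1, PCF11, PLK1 and SEC31B, which share at least 10% of exonic bases with another gene.

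**Figure D1:**
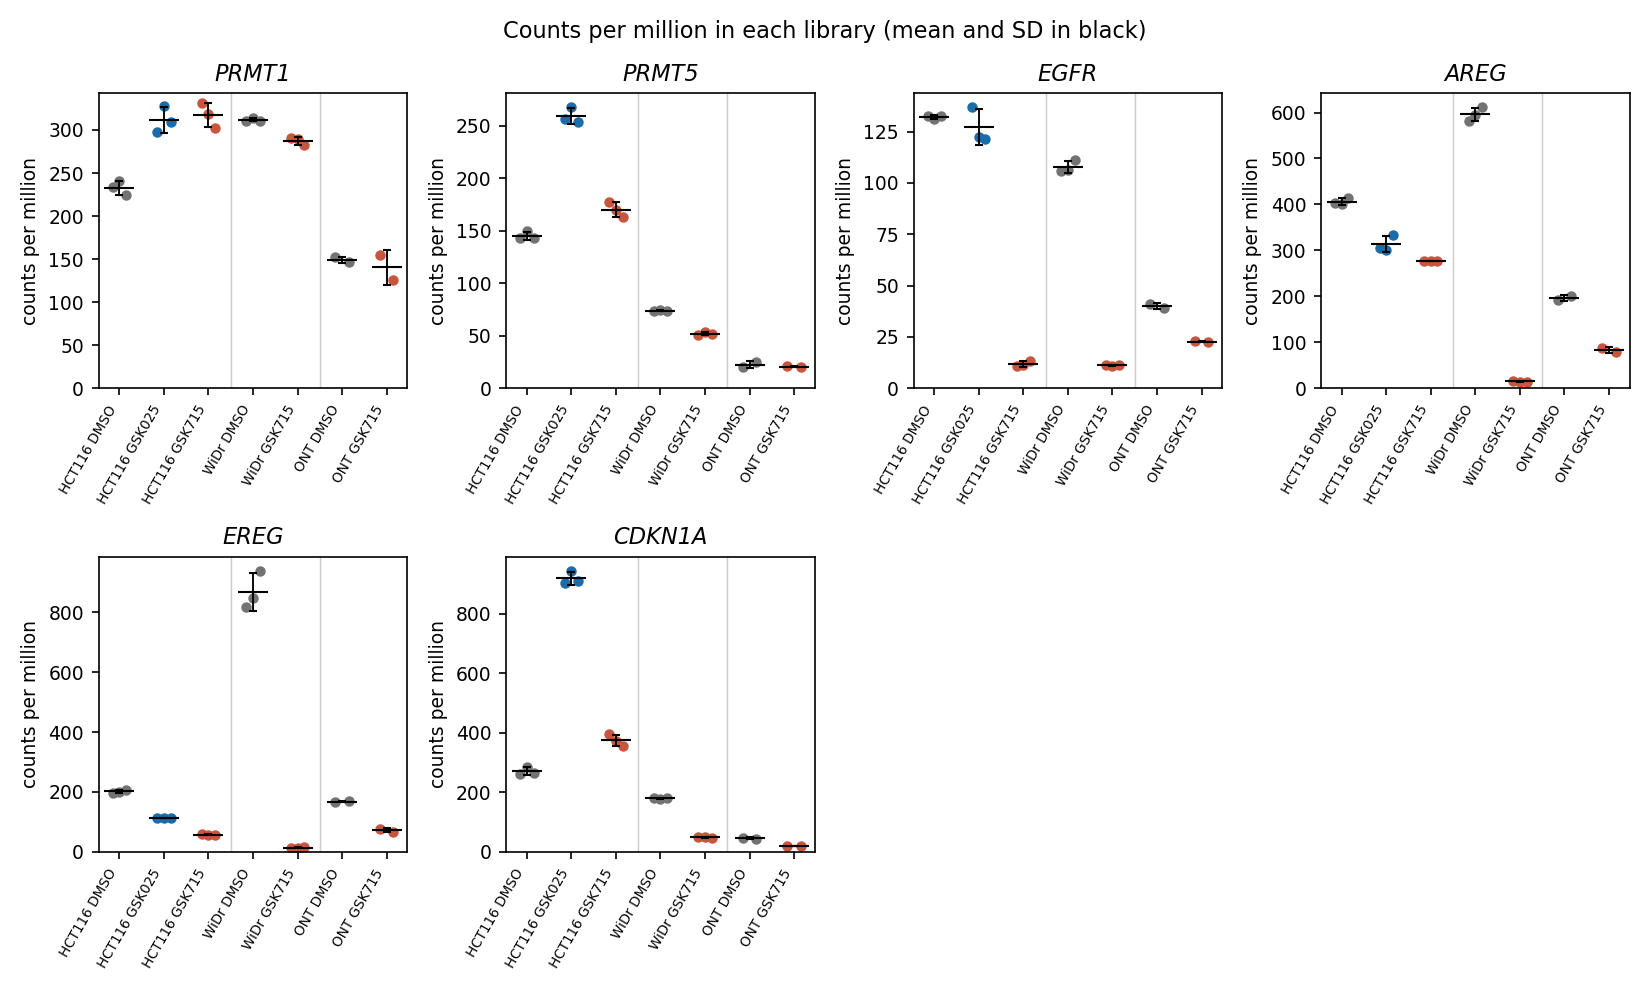
CPM (y axes, linear from 0) of PRMT1, PRMT5, EGFR, AREG, EREG and CDKN1A in each library by group, with the mean and SD in black (n = 3 per group, n = 2 for ONT). EGFR stood at 132 ± 0.976 CPM with DMSO in HCT116, 127 ± 8.80 with GSK025 and 11.8 ± 1.41 with GSK715.

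With GSK025 in HCT116, the comparison asks which transcripts change when PRMT5 is inhibited. SLC2A1, the glucose transporter GLUT1, rose from 86.5 ± 1.10 to 407 ± 16.5 CPM, and INPP5D, an inositol phosphatase best known from blood cells, from 2.04 ± 0.231 to 17.7 ± 1.06 CPM (n = 3). MALAT1, an abundant nuclear long noncoding RNA, fell 7.09-fold. DNA damage and growth arrest genes rose together, among them CDKN1A, the cell cycle inhibitor p21, which reached 918 ± 22.3 CPM from 271 ± 12.7. Mitotic genes fell, while members of the spliceosome core and of ribosome biogenesis rose. In total 8708 of 19751 genes passed in edgeR, 4338 higher and 4370 lower (3650 and 4900 with library totals). With TMM, 266 rose and 1485 fell at least 2-fold.

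Among the largest increases by the fixed rule were DERPC (log2FC 3.23, SE 0.52), whose gene model is absent from the annotation and whose 3 treated libraries spread from 8.50 to 21.1 CPM, INPP5D (log2FC 3.12, SE 0.16) and the collagen chain COL6A3 (log2FC 2.39, SE 0.45). SLC2A1 (log2FC 2.23, SE 0.056), the arginine deiminase PADI3 (log2FC 2.09, SE 0.14) and the histone gene H2BC5 (log2FC 2.05, SE 0.18) followed, the last with near-identical family members that make its level uncertain. Among the largest decreases were MALAT1 (ENSG00000251562, GRCh38 chromosome 11, 65497688 to 65506516, log2FC -2.83, SE 0.15), the homeobox factor ONECUT2 (log2FC -2.82, SE 0.19) and NABP1, which binds single-stranded DNA (log2FC -2.78, SE 0.11).

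Among the DNA damage and growth arrest genes (the list of p53 targets), 18 of 29 measured rose, 3 fell and 8 did not pass. Their median was 0.47 (camera adjusted p = 7.4e-12, and 0.0044 with an estimated correlation). CDKN1A (log2FC 1.76, SE 0.047) and the secreted factor GDF15 (log2FC 1.60, SE 0.047) led the increases, while RRM2B, a ribonucleotide reductase subunit (log2FC -0.48, SE 0.064), and the ubiquitin ligase MDM2 (log2FC -0.45, SE 0.084), fell. For mitotic genes, 4 of 30 measured rose, 20 fell and 6 did not pass (6 and 21 adjusted over the list alone). Their median was -0.33 (camera adjusted p = 9.4e-05, and 0.0495 with an estimated correlation). ANLN, which works at the cleavage furrow (log2FC -1.16, SE 0.051), and the topoisomerase TOP2A (log2FC -1.17, SE 0.074) fell, whereas the kinase PLK1 (log2FC 0.52, SE 0.051) rose. Of the homologous recombination and Fanconi genes, 4 of 31 measured rose, 20 fell and 7 did not pass (4 and 21 adjusted over the list alone). Their median was -0.74 (camera adjusted p = 0.00019, but adjusted p = 0.072 with an estimated correlation). The damage kinases ATR (log2FC -2.20, SE 0.12) and ATM (log2FC -2.18, SE 0.13) fell 4.59-fold and 4.53-fold, and RAD51C rose (log2FC 0.47, SE 0.082). Fold change fell with exonic length here (rho -0.301 over genes of at least 5 CPM), a possible sign of RNA quality that includes long genes such as ATM and ATR. In the list of DNA replication genes, 14 of 32 measured rose, 6 fell and 12 did not pass (15 and 6 adjusted over the list alone). Their median was 0.21 (camera adjusted p = 0.0179, but adjusted p = 0.157 with an estimated correlation). MCM7, a subunit of the replicative helicase (log2FC 0.60, SE 0.042), rose and RFC4, a clamp loader subunit (log2FC -0.26, SE 0.059), fell.

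In the snRNP and spliceosome core, 19 of 29 measured rose, 1 fell and 9 did not pass (20 and 1 adjusted over the list alone). Their median was 0.37 (camera adjusted p = 8.9e-08, and 0.0495 with an estimated correlation). The scaffold protein PRPF8 (log2FC 0.94, SE 0.053) and the polypyrimidine tract binder U2AF2 (log2FC 0.99, SE 0.063) rose, and the branch site factor SF3B1 fell (log2FC -0.47, SE 0.046). SR protein and hnRNP splicing factors were split, as 17 of 34 measured rose, 10 fell and 7 did not pass (18 and 10 adjusted over the list alone, camera adjusted p = 0.0716). TAF15, an RNA-binding protein, fell (log2FC -0.81, SE 0.035). For ribosome biogenesis genes, 19 of 26 measured rose, 3 fell and 4 did not pass (19 and 4 adjusted over the list alone). Their median was 0.31 (camera adjusted p = 0.0012, and 0.0495 with an estimated correlation), with PES1 rising (log2FC 0.78, SE 0.045) and GNL3 falling (log2FC -0.48, SE 0.04). In the PRMT list, 8 of 12 measured rose, 1 fell and 3 did not pass. Their median was 0.44 (camera adjusted p = 0.0085, but adjusted p = 0.0685 with an estimated correlation). PRMT9 fell (log2FC -0.98, SE 0.12). In methionine and SAM metabolism, 7 of 22 measured rose, 6 fell and 9 did not pass (8 and 6 adjusted over the list alone, camera adjusted p = 0.402). MAT2A, which makes the methyl donor S-adenosylmethionine, fell (log2FC -1.38, SE 0.038) and AHCY, which clears its product, rose (log2FC 0.67, SE 0.043).

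Endoplasmic reticulum chaperones moved down, and 2 of 18 measured rose, 11 fell and 5 did not pass (2 and 12 adjusted over the list alone). Their median was -0.16 (camera adjusted p = 0.0022, but adjusted p = 0.0658 with an estimated correlation). The chaperones HSPA5 (log2FC -0.66, SE 0.027) and HSP90B1 (log2FC -0.87, SE 0.041) fell. Of the mitochondrially encoded genes, 0 of 13 measured rose, 12 fell and 1 did not pass. Their median was -0.72 (camera adjusted p = 3.5e-19, but adjusted p = 0.0587 with an estimated correlation), and their share of all counts went from between 8.64% and 9.09% with DMSO to between 5.13% and 5.48%. For Wnt target and crypt stem cell genes, 10 of 18 measured rose, 4 fell and 4 did not pass. Their median was 0.43 (camera adjusted p = 0.0253, but adjusted p = 0.326 with an estimated correlation), and BMP4 (log2FC 1.03, SE 0.049) and SOX9 (log2FC 0.64, SE 0.039) rose and the Wnt antagonist DKK1 (log2FC -1.10, SE 0.037) fell. Of the replication-dependent histone genes, 5 of 14 measured rose, 0 fell and 9 did not pass. Their median was 0.97 (camera adjusted p = 0.0338, but adjusted p = 0.112 with an estimated correlation). The list did not pass without DMSO replicate 1 or 3 or GSK025 replicate 2 or 3 (adjusted p = 0.0613, 0.0502, 0.0617 and 0.084). Histone transcripts lack poly(A) tails, and their genes are near-identical. The other lists did not pass (camera adjusted p from 0.0625 to 0.968), and counts for these are of members that rose and fell. Interferon-stimulated genes had 4 and 15 of 36 (4 and 16 adjusted over the list alone), MHC class I antigen presentation 2 and 2 of 15 and cleavage and polyadenylation factors 12 and 7 of 26 (14 and 7 adjusted over the list alone). ATF4 and amino acid response genes had 13 and 5 of 27 (14 and 5 adjusted over the list alone), sterol synthesis genes 9 and 11 of 24 and NF-kB and inflammatory genes 8 and 5 of 23. Mesenchymal transition genes had 9 and 5 of 25 (9 and 6 adjusted over the list alone). Absorptive colonocyte markers had 1 and 2 of 11, goblet cell markers 1 and 1 of 12 (0 and 1 adjusted over the list alone) and enteroendocrine markers 1 and 1 of 8. Markers of stromal, endothelial and immune cells had 3 and 1 of 13. PCSK1N, a neuroendocrine peptide, had no counts with DMSO and was at least 17.1-fold higher with GSK025. Median, mean and test differed in sign for methionine and SAM metabolism (median 0.079, mean -0.041, test down), ATF4 and amino acid response genes (0.17, -0.12, up), NF-kB and inflammatory genes (0.032, -0.29, up), mesenchymal transition genes (0.15, -0.066, up), the absorptive colonocyte markers (-0.33, -0.12, up) and MHC class I antigen presentation (-0.026, 0.022, up).

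With GSK715 in HCT116, the question was which transcripts change when type I enzymes are inhibited. EGFR, the receptor of epidermal growth factor, fell from 132 ± 0.976 to 11.8 ± 1.41 CPM, and NT5E, the surface enzyme CD73, from 65.4 ± 1.46 to 5.71 ± 0.792 CPM (n = 3). CCN2, a matrix protein induced by YAP and TGF-beta signals, rose 5.48-fold. Genes of the ATF4 and amino acid response and the endoplasmic reticulum chaperones rose, while SR protein and hnRNP splicing factors and mitotic genes fell. A total of 9157 of 19751 genes passed, 4372 higher and 4785 lower, and 527 rose and 1692 fell at least 2-fold. With library totals alone the median of all genes moved by -0.16 against TMM scaling, which left 2994 genes higher and 6343 lower.

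By the fixed rule the largest increases were SNHG19, a host gene of a small nucleolar RNA (log2FC 2.86, SE 0.084), the long noncoding RNA FOXD2-AS1 (log2FC 2.80, SE 0.19) and the hair keratin-associated gene KRTAP2-3 (log2FC 2.62, SE 0.082), which has near-identical family members. MYEOV (log2FC 2.52, SE 0.047), CCN2 (log2FC 2.45, SE 0.081) and the epithelial keratin KRT80 (log2FC 2.42, SE 0.092) followed. LMF1, which matures lipases, fell most (log2FC -3.64, SE 0.23). NT5E (log2FC -3.52, SE 0.089) and EGFR (ENSG00000146648, GRCh38 chromosome 7, 55019021 to 55211628, log2FC -3.49, SE 0.079) came next, then the calcium channel ITPR2 (log2FC -3.31, SE 0.18), the autophagy gene ATG2B (log2FC -3.20, SE 0.24) and CCDC92 (log2FC -3.18, SE 0.21).

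In the list of ATF4 and amino acid response genes, 22 of 27 measured rose, 2 fell and 3 did not pass. Their median was 0.87 (camera adjusted p = 9.1e-26, and 0.0055 with an estimated correlation). ASNS, which makes asparagine (log2FC 1.40, SE 0.036), and DDIT4, an inhibitor of mTORC1 signalling (log2FC 1.34, SE 0.038), rose, and the cystine transporter SLC7A11 (log2FC -1.08, SE 0.15) fell. Of the endoplasmic reticulum chaperones, 13 of 18 measured rose, 1 fell and 4 did not pass (13 and 2 adjusted over the list alone). Their median was 0.58 (camera adjusted p = 1.2e-14, and 0.0055 with an estimated correlation). HSPA5, the chaperone BiP, rose from 2081 ± 8.57 to 7077 ± 78.9 CPM (log2FC 1.77, SE 0.028), and HERPUD1, of the degradation pathway, rose as well (log2FC 1.48, SE 0.045). Of the mesenchymal transition genes, 12 of 25 measured rose, 3 fell and 10 did not pass (13 and 3 adjusted over the list alone). Their median was 0.35 (camera adjusted p = 2.8e-05, and 0.0117 with an estimated correlation), with CCN1 (log2FC 2.10, SE 0.055) beside CCN2, whereas the integrin ITGAV fell (log2FC -0.74, SE 0.061). For DNA damage and growth arrest genes, 18 of 29 measured rose, 7 fell and 4 did not pass. Their median was 0.39 (camera adjusted p = 8.3e-05, and 0.0127 with an estimated correlation). FDXR, of mitochondrial electron transfer (log2FC 1.32, SE 0.052), and the kinase PLK3 (log2FC 1.06, SE 0.045) rose, and RRM2B fell (log2FC -1.05, SE 0.065). Within MHC class I antigen presentation, 9 of 15 measured rose, 1 fell and 5 did not pass. Their median was 0.37 (camera adjusted p = 7.4e-05, and 0.0398 with an estimated correlation). HLA-B (log2FC 0.94, SE 0.036) and HLA-C (log2FC 0.73, SE 0.038) rose, with the reserve that reads of HLA genes are hard to place, and the chaperone TAPBP fell (log2FC -0.39, SE 0.053).

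Of the SR protein and hnRNP splicing factors, 7 of 34 measured rose, 20 fell and 7 did not pass. Their median was -0.32 (camera adjusted p = 1.9e-07, and 0.0113 with an estimated correlation). The SR protein SRSF3 (log2FC -1.49, SE 0.047) fell, while HNRNPA1 (log2FC 0.77, SE 0.027) and HNRNPL (log2FC 0.65, SE 0.044) rose. In the snRNP and spliceosome core, 23 of 29 measured rose, 1 fell and 5 did not pass. Their median was 0.28 (camera adjusted p = 0.00059, but adjusted p = 0.132 with an estimated correlation), with LSM4 (log2FC 0.60, SE 0.049) and SF3A1 (log2FC 0.48, SE 0.041) among those that rose. Of the mitotic genes, 2 of 30 measured rose, 22 fell and 6 did not pass. Their median was -0.48 (camera adjusted p = 5.4e-08, and 0.0088 with an estimated correlation). ANLN (log2FC -1.27, SE 0.051) and the spindle motor KIF11 (log2FC -1.52, SE 0.083) fell. Of the recombination and Fanconi genes, 4 of 31 measured rose, 16 fell and 11 did not pass (4 and 17 adjusted over the list alone). Their median was -0.48 (camera adjusted p = 0.0319, but adjusted p = 0.241 with an estimated correlation), with ATM (log2FC -1.91, SE 0.13) and ATR (log2FC -1.53, SE 0.12) lower. The same reserve on length holds here (rho -0.292). For the mitochondrially encoded genes, 0 of 13 measured rose, 12 fell and 1 did not pass. Their median was -0.69 (camera adjusted p = 3e-17, but adjusted p = 0.0514 with an estimated correlation), at a share of 5.09% to 5.42% of all counts.

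The other lists did not pass (camera adjusted p from 0.217 to 0.979), with members that rose and fell as follows. The PRMT family and PRMT5 complex had 5 and 4 of 12, methionine and SAM metabolism 12 and 6 of 22 and interferon-stimulated genes 6 and 10 of 36. DNA replication genes had 13 and 7 of 32, Wnt target and crypt stem cell genes 5 and 5 of 18 and cleavage and polyadenylation factors 5 and 14 of 26. Sterol synthesis genes had 5 and 9 of 24. Ribosome biogenesis genes had 7 and 12 of 26 (8 and 13 adjusted over the list alone), NF-kB and inflammatory genes 7 and 3 of 23 and replication-dependent histone genes 0 and 3 of 14. Absorptive colonocyte markers had 1 and 4 of 11, goblet cell markers 0 and 1 of 12 and enteroendocrine markers 3 and 1 of 8. Markers of stromal, endothelial and immune cells had 2 and 1 of 13. Single members of these lists still changed: the interferon factor IRF7 rose (log2FC 1.27, SE 0.08), the poly(A)-binding protein PABPN1 rose (log2FC 1.11, SE 0.063) and the termination factor PCF11 fell (log2FC -1.39, SE 0.083). MAT2A fell again (log2FC -0.96, SE 0.038), and SAT1, which acetylates spermidine and spermine, rose (log2FC 0.87, SE 0.04). PCSK1N was at least 21.2-fold higher than with DMSO, where it had no counts. Signs of median, mean and test differed for the PRMT list (0.039, -0.054, up), interferon-stimulated genes (0.12, -0.033, down), Wnt targets (0.082, -0.041, down), goblet cell markers (-0.04, 0.05, up) and stromal, endothelial and immune cell markers (0.13, -0.45, up).

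Set against each other in HCT116, the inhibitors parted at the stress response and at splicing factors, although their doses differed (5 and 10 µM), so the contrast is of these treatments and not of matched exposures. HSPA5 stood at 7077 ± 78.9 CPM with GSK715 and 1313 ± 32.4 with GSK025 (n = 3). EGFR was at 127 ± 8.80 CPM with GSK025, where its change against DMSO did not pass (log2FC -0.057, SE 0.07, adjusted p = 0.56), and 10.8-fold lower with GSK715. Of 19751 genes, 8746 differed, 4302 higher and 4444 lower with GSK715, of which 988 and 1144 at least 2-fold. With library totals these became 3474 and 5406.

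Largest in favour of GSK715 were FAM47E-STBD1 (log2FC 4.78, SE 1.05), a readthrough gene whose reads belong in part to its neighbours, the pseudogene FAUP4 (log2FC 3.30, SE 0.25) and CHAC1, which degrades glutathione under ATF4 (log2FC 3.05, SE 0.15). The carboxypeptidase CPA4 (log2FC 2.86, SE 0.041), the paraspeckle RNA NEAT1 (log2FC 2.55, SE 0.054) and the kinase MAPK15 (log2FC 2.49, SE 0.14) came next. Among the largest in favour of GSK025 were LMF1 (log2FC -4.04, SE 0.24), NT5E (log2FC -3.75, SE 0.089), CCDC92 (log2FC -3.60, SE 0.21), WWC3, a regulator of the Hippo pathway (log2FC -3.53, SE 0.15), and EGFR (log2FC -3.43, SE 0.079).

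Endoplasmic reticulum chaperones were higher with GSK715, where 17 of 18 measured were higher, 1 lower and 0 did not pass. Their median was 0.69 (camera adjusted p = 2.2e-29, and 0.001 with an estimated correlation). In the ATF4 and amino acid response list, 19 of 27 measured were higher, 1 lower and 7 did not pass (20 and 1 adjusted over the list alone). Their median was 0.67 (camera adjusted p = 3.3e-23, and 0.0045 with an estimated correlation), with ASNS the clearest (log2FC 1.85, SE 0.036). SR protein and hnRNP splicing factors were lower, and 4 of 34 measured were higher, 22 lower and 8 did not pass (4 and 23 adjusted over the list alone). Their median was -0.33 (camera adjusted p = 2.7e-13, and 0.0035 with an estimated correlation). SRSF3 was lower (log2FC -1.85, SE 0.047) and TAF15 higher (log2FC 0.54, SE 0.035). Ribosome biogenesis genes were lower, since 3 of 26 measured were higher, 18 lower and 5 did not pass (4 and 19 adjusted over the list alone). Their median was -0.47 (camera adjusted p = 7.4e-05, and 0.0164 with an estimated correlation), with nucleolin (NCL) lower (log2FC -0.53, SE 0.033). For mesenchymal transition genes, 8 of 25 measured were higher, 0 lower and 17 did not pass. Their median was 0.24 (camera adjusted p = 0.00048, and 0.0249 with an estimated correlation). Among DNA damage and growth arrest genes, 8 of 29 measured were higher, 18 lower and 3 did not pass (8 and 19 adjusted over the list alone). Their median was -0.36 (camera adjusted p = 0.0233, but adjusted p = 0.0704 with an estimated correlation), and CDKN1A was lower with GSK715 (log2FC -1.30, SE 0.046). Within MHC class I antigen presentation, 7 of 15 measured were higher, 2 lower and 6 did not pass. Their median was 0.35 (camera adjusted p = 0.00034, but adjusted p = 0.0638 with an estimated correlation). For Wnt target and crypt stem cell genes, 4 of 18 measured were higher, 12 lower and 2 did not pass. Their median was -0.27 (camera adjusted p = 0.0014, but adjusted p = 0.148 with an estimated correlation), with BMP4 lower (log2FC -1.61, SE 0.05). Of the cleavage and polyadenylation factors, 3 of 26 measured were higher, 17 lower and 6 did not pass (4 and 17 adjusted over the list alone). Their median was -0.28 (camera adjusted p = 0.0233, but adjusted p = 0.0704 with an estimated correlation), with the kinase CDK12 lower (log2FC -0.96, SE 0.067). Of the replication-dependent histone genes, 0 of 14 measured were higher, 7 lower and 7 did not pass (0 and 8 adjusted over the list alone). Their median was -1.11 (camera adjusted p = 0.0093, but adjusted p = 0.0683 with an estimated correlation).

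No other list passed between the inhibitors (camera adjusted p from 0.0541 to 0.834), and counts are of members higher and lower with GSK715. The PRMT family and PRMT5 complex had 1 and 7 of 12 (2 and 7 adjusted over the list alone), methionine and SAM metabolism 8 and 4 of 22 and interferon-stimulated genes 12 and 7 of 36 (12 and 8 adjusted over the list alone). DNA replication genes had 6 and 14 of 32, mitotic genes 4 and 13 of 30 (5 and 13 adjusted over the list alone) and homologous recombination and Fanconi genes 14 and 4 of 31. The snRNP and spliceosome core had 6 and 14 of 29 (7 and 15 adjusted over the list alone). Sterol synthesis genes had 8 and 7 of 24 (8 and 8 adjusted over the list alone), NF-kB and inflammatory genes 9 and 6 of 23 and mitochondrially encoded genes 3 and 3 of 13. Absorptive colonocyte markers had 1 and 3 of 11, goblet cell markers 1 and 2 of 12 and enteroendocrine markers 1 and 1 of 8. Markers of stromal, endothelial and immune cells had 2 and 3 of 13 (2 and 2 adjusted over the list alone). The methionine list had a median of -0.016 beside a mean of 0.098 and a test up. Both inhibitors were compared with the same DMSO libraries, which alone makes their fold changes correlate. Across 19751 genes, which are not independent replicates, r was 0.381 and Spearman's rho 0.425. Simulated groups without any effect but with shared controls gave a median r of 0.502 and rho of 0.431 over 20 simulations. The covariance was 0.433, against 0.192 simulated, and over genes of at least 5 CPM 0.212 against 0.0101 (r 0.566 against 0.508). Of 5987 genes called under both, 2455 rose and 2500 fell under each, where independent calls would give 960.2 and 1059, and 1032 went opposite ways. The expected numbers ignore the shared controls.

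In WiDr, GSK715 was compared with DMSO in the same way. EREG and AREG, which code for the EGF receptor ligands epiregulin and amphiregulin, fell from 868 ± 63.2 to 14.3 ± 1.32 CPM and from 596 ± 14.5 to 14.8 ± 0.95 CPM (n = 3), and EGFR itself from 108 ± 3.01 to 11.3 ± 0.273 CPM (log2FC -3.26, SE 0.042, adjusted p = 9.9e-12). All 30 mitotic genes fell, as did nearly the whole list of ATF4 and amino acid response genes. In total 12727 of 19340 genes passed, 6502 higher and 6225 lower, and 3376 rose and 2027 fell at least 2-fold. Library totals moved the median of all genes by 0.12, with 7495 higher and 5300 lower.

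The largest increases were POGLUT2P1 (log2FC 6.99, SE 0.43), a pseudogene whose reads are not told apart here from those of its parent gene, the organic anion transporter SLCO2B1 (log2FC 6.34, SE 0.19), BNIP5 (log2FC 5.89, SE 0.35), the surface protein CD109 (log2FC 5.66, SE 0.28), LASP1NB (log2FC 5.41, SE 0.12) and PIGR, which carries antibodies across epithelia (log2FC 5.18, SE 0.35). The largest decreases were the chloride channel relative ANO3 (log2FC -6.99, SE 0.46), APCDD1L (log2FC -6.73, SE 0.20) with its divergent transcript APCDD1L-DT (log2FC -5.60, SE 0.18), EREG (ENSG00000124882, GRCh38 chromosome 4, 74365143 to 74388751, log2FC -5.92, SE 0.079), AREG (ENSG00000109321, GRCh38 chromosome 4, 74445134 to 74455009, log2FC -5.33, SE 0.051) and the netrin receptor UNC5B (log2FC -5.25, SE 0.086).

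Of the mitotic genes, 0 of 30 measured rose, 30 fell and 0 did not pass. Their median was -1.32 (camera adjusted p = 5.6e-28, and 0.0053 with an estimated correlation). The spindle factor TPX2 (log2FC -1.85, SE 0.036) and the cyclin CCNB1 (log2FC -1.56, SE 0.031) fell. Among DNA replication genes, 12 of 32 measured rose, 11 fell and 9 did not pass (camera adjusted p = 0.734), with the licensing factor CDT1 rising (log2FC 1.60, SE 0.053) and RFC3 falling (log2FC -1.49, SE 0.048). In the ATF4 and amino acid response list, 1 of 26 measured rose, 23 fell and 2 did not pass. Their median was -1.56 (camera adjusted p = 7e-36, and 0.0065 with an estimated correlation). The tryptophanyl-tRNA synthetase WARS1 (log2FC -2.68, SE 0.027) and ASNS (log2FC -2.61, SE 0.027) fell, and NUPR1, a stress-induced chromatin protein (log2FC 2.57, SE 0.058), rose. For endoplasmic reticulum chaperones, 2 of 18 measured rose, 13 fell and 3 did not pass. Their median was -0.31 (camera adjusted p = 0.0431, but adjusted p = 0.189 with an estimated correlation). HSPA5 fell (log2FC -0.98, SE 0.019) and CALR, calreticulin, rose (log2FC 0.96, SE 0.026), and the list's call ended with library totals (adjusted p = 0.0989). Splicing factors of the SR protein and hnRNP list fell, as 3 of 34 measured rose, 29 fell and 2 did not pass (3 and 30 adjusted over the list alone). Their median was -0.56 (camera adjusted p = 1.2e-10, and 0.0277 with an estimated correlation), with SRSF7 lower (log2FC -1.55, SE 0.029). Of the ribosome biogenesis genes, 2 of 26 measured rose, 24 fell and 0 did not pass. Their median was -0.93 (camera adjusted p = 8.6e-11, but adjusted p = 0.0606 with an estimated correlation), with NOP58 (log2FC -1.79, SE 0.038) and dyskerin, DKC1 (log2FC -1.21, SE 0.028), of the small nucleolar ribonucleoproteins lower. Of the cleavage and polyadenylation factors, 4 of 26 measured rose, 17 fell and 5 did not pass (4 and 18 adjusted over the list alone). Their median was -0.39 (camera adjusted p = 0.0109, but adjusted p = 0.151 with an estimated correlation), with CPSF2 (log2FC -1.26, SE 0.043) below its DMSO level.

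Of the MHC class I antigen presentation genes, 13 of 15 measured rose, 1 fell and 1 did not pass. Their median was 0.59 (camera adjusted p = 0.00054, but adjusted p = 0.206 with an estimated correlation). HLA-E (log2FC 0.96, SE 0.032) and TAPBP (log2FC 1.08, SE 0.052) rose. Interferon-stimulated genes went down instead, as 5 of 36 measured rose, 26 fell and 5 did not pass. Their median was -0.53 (camera adjusted p = 0.008, but adjusted p = 0.239 with an estimated correlation), with OASL (log2FC -1.58, SE 0.037) and the RNA sensor IFIH1 (log2FC -1.98, SE 0.069) lower. For DNA damage and growth arrest genes, 7 of 29 measured rose, 14 fell and 8 did not pass. Their median was -0.054 (camera adjusted p = 0.0091, but adjusted p = 0.151 with an estimated correlation). GDF15 (log2FC -2.41, SE 0.036) and CDKN1A (log2FC -1.88, SE 0.032) fell, and the antiproliferative gene BTG2 rose (log2FC 2.46, SE 0.072). Within methionine and SAM metabolism, 7 of 21 measured rose, 10 fell and 4 did not pass. Their median was -0.18 (camera adjusted p = 0.0431, but adjusted p = 0.189 with an estimated correlation). ODC1, which makes putrescine (log2FC -1.87, SE 0.024), and MAT2A (log2FC -0.86, SE 0.023) fell, and the call ended with library totals (adjusted p = 0.105), with the replicate block (0.0782) and without GSK715 replicate 3 (0.0538). In the list of stromal, endothelial and immune cell markers, 5 of 8 measured rose, 2 fell and 1 did not pass (6 and 2 adjusted over the list alone). Their median was 1.32 (camera adjusted p = 0.0431, but adjusted p = 0.383 with an estimated correlation). The members that rose included LYZ, lysozyme, which secretory cells of the gut also make (log2FC 1.35, SE 0.022), and CD14 (log2FC 1.40, SE 0.096). Without DMSO replicate 2 the adjusted p was 0.0524, and with the replicate block 0.0559.

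Lists that did not pass (camera adjusted p from 0.0592 to 0.698) still held many members that rose or fell, counted here in this order. The PRMT family and PRMT5 complex had 4 and 7 of 12, homologous recombination and Fanconi genes 6 and 19 of 31 and the snRNP and spliceosome core 7 and 17 of 29 (7 and 18 adjusted over the list alone). Sterol synthesis genes had 13 and 6 of 24, NF-kB and inflammatory genes 9 and 10 of 24 (10 and 10 adjusted over the list alone) and mesenchymal transition genes 6 and 9 of 21. Mitochondrially encoded genes had 9 and 1 of 13 (10 and 1 adjusted over the list alone). Replication-dependent histone genes had 4 and 2 of 14 (3 and 2 adjusted over the list alone), Wnt target and crypt stem cell genes 11 and 8 of 20 and absorptive colonocyte markers 10 and 5 of 16. Goblet cell markers had 5 and 5 of 15 and enteroendocrine markers 4 and 0 of 7. MYC (log2FC -2.03, SE 0.033) and the cyclin CCND1 (log2FC -1.25, SE 0.03) fell and the stem cell marker PROM1 rose (log2FC 2.56, SE 0.029). Of the colonocyte markers, MUC12 rose (log2FC 2.85, SE 0.11) and CEACAM5 fell (log2FC -1.77, SE 0.035), and of the goblet cell markers MUC5AC fell (log2FC -2.00, SE 0.04). INSIG1, a brake on sterol synthesis, rose (log2FC 2.89, SE 0.10), and so did the adhesion receptor ICAM1 (log2FC 3.53, SE 0.073). ALPI, intestinal alkaline phosphatase, had no counts with DMSO and was at least 35.6-fold higher with GSK715. Mitochondrially encoded genes made up 6.07% to 6.49% of counts with DMSO and 8.30% to 8.83% with GSK715. Signs of median, mean and test differed for goblet cell markers (0.087, 0.05, down), NF-kB and inflammatory genes (-0.0057, 0.25, up) and mesenchymal transition genes (0.034, -0.35, down).

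**Figure D2:**
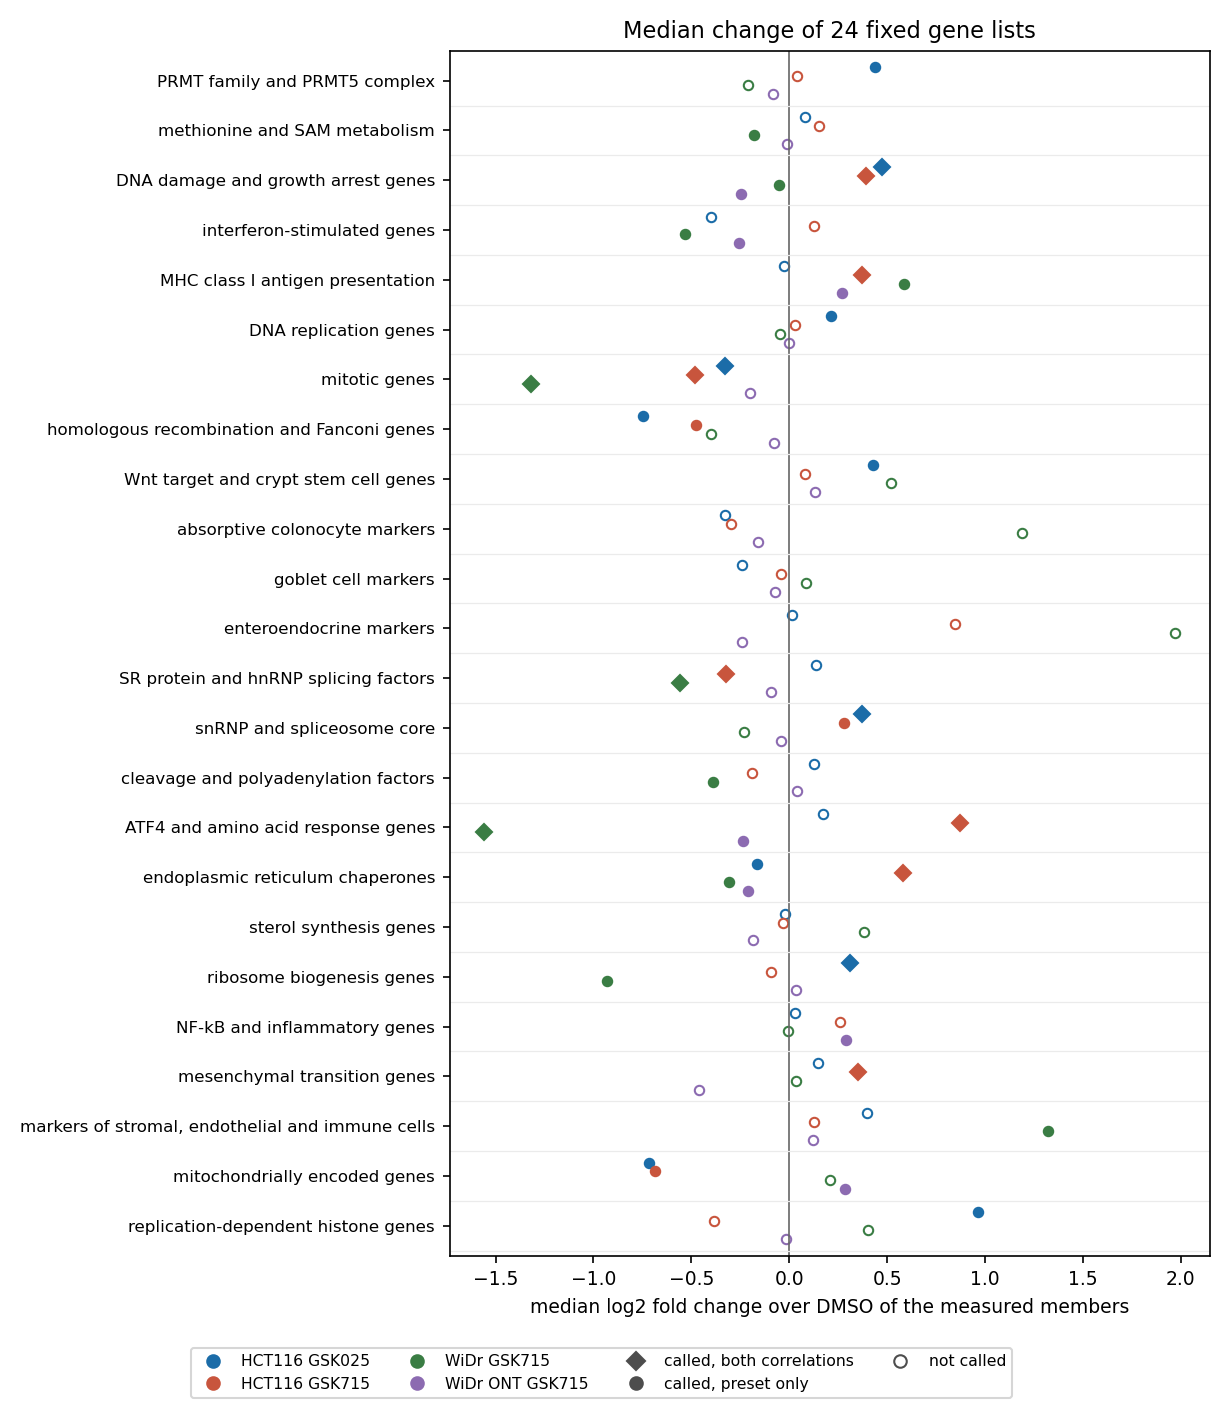
Median log2 fold change over DMSO (x axis) of the measured members of each of the 24 fixed gene lists (y axis) in the 4 comparisons with DMSO. Filled symbols passed the camera test, diamonds also with an estimated correlation; the ATF4 and amino acid response genes stood at 0.87 in HCT116 and -1.56 in WiDr with GSK715.

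How the GSK715 response differs between the lines was tested as an interaction, WiDr minus HCT116. The ATF4 and amino acid response genes showed the widest gap of all lists: ASNS rose from 232 ± 0.139 to 615 ± 19.2 CPM in HCT116 and fell from 1058 ± 4.85 to 173 ± 4.71 CPM in WiDr. HSPA5 rose in HCT116 (1.77) and fell in WiDr (-0.98), and so did CCN2 (2.45 and -2.46). The response differed at 10187 of 21791 genes, with 5058 differences above and 5129 below 0. Library totals moved the median difference of all genes by 0.35 and left 7321 above and 3203 below. The tables of the lines were counted separately, so CPM are not compared between them.

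In the ATF4 and amino acid response list, 1 of 27 measured were above 0, 25 below 0 and 1 did not pass. Their median was -2.52 (camera adjusted p = 1.3e-95, and 1.1e-05 with an estimated correlation). ASNS (log2FC -4.08, SE 0.04) and WARS1 (log2FC -3.31, SE 0.044) were below. Of the endoplasmic reticulum chaperones, 0 of 18 measured were above 0, 14 below 0 and 4 did not pass (1 and 14 adjusted over the list alone). Their median was -0.81 (camera adjusted p = 6.4e-15, and 0.00097 with an estimated correlation), with HSPA5 at -2.82. For mitotic genes, 3 of 30 measured were above 0, 23 below 0 and 4 did not pass (4 and 23 adjusted over the list alone). Their median was -0.88 (camera adjusted p = 1.3e-10, and 0.00076 with an estimated correlation), so the decrease was the larger in the WiDr short reads. This and the ATF4 gap rest on short reads, since ONT minus short reads in WiDr had medians of 1.26 and 1.34. For ribosome biogenesis genes, 1 of 26 measured were above 0, 21 below 0 and 4 did not pass. Their median was -0.73 (camera adjusted p = 3.3e-09, and 0.0043 with an estimated correlation). For DNA damage and growth arrest genes, 7 of 29 measured were above 0, 17 below 0 and 5 did not pass (7 and 18 adjusted over the list alone). Their median was -0.72 (camera adjusted p = 3.7e-08, and 0.0016 with an estimated correlation), with GDF15 at -3.45 (SE 0.06). Of the mesenchymal transition genes, 3 of 25 measured were above 0, 12 below 0 and 10 did not pass (4 and 12 adjusted over the list alone). Their median was -0.64 (camera adjusted p = 0.00016, and 0.0076 with an estimated correlation), with CCN2 at -4.98. In methionine and SAM metabolism, 5 of 22 measured were above 0, 12 below 0 and 5 did not pass. Their median was -0.35 (camera adjusted p = 0.0027, and 0.0216 with an estimated correlation), and ODC1 was below 0 (log2FC -2.35, SE 0.043). Of the SR protein and hnRNP splicing factors, 7 of 34 measured were above 0, 22 below 0 and 5 did not pass. Their median was -0.33 (camera adjusted p = 0.0002, and 0.0137 with an estimated correlation). With library totals the adjusted p became 0.343 for this list and 0.138 for the methionine list. In the snRNP core, 3 of 29 measured were above 0, 22 below 0 and 4 did not pass. Their median was -0.61 (camera adjusted p = 0.00043, but adjusted p = 0.0831 with an estimated correlation). This call also ended with library totals (adjusted p = 0.109). Of the sterol synthesis genes, 13 of 24 measured were above 0, 7 below 0 and 4 did not pass. Their median was 0.36 (camera adjusted p = 0.0393, but adjusted p = 0.198 with an estimated correlation). Of the mitochondrially encoded genes, 13 of 13 measured were above 0, 0 below 0 and 0 did not pass. Their median was 0.96 (camera adjusted p = 8.6e-11, but adjusted p = 0.0763 with an estimated correlation).

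The other lists did not pass (camera adjusted p from 0.0662 to 0.597), with members above and below 0 as follows. The PRMT family and PRMT5 complex had 4 and 8 of 12, interferon-stimulated genes 5 and 21 of 36 (6 and 21 adjusted over the list alone) and MHC class I antigen presentation 6 and 5 of 15. DNA replication genes had 7 and 13 of 32 (8 and 14 adjusted over the list alone), homologous recombination and Fanconi genes 9 and 9 of 31 and Wnt target and crypt stem cell genes 11 and 8 of 21. Cleavage and polyadenylation factors had 5 and 13 of 26, NF-kB and inflammatory genes 7 and 10 of 24 and replication-dependent histone genes 5 and 1 of 16. Absorptive colonocyte markers had 5 and 2 of 16 (6 and 2 adjusted over the list alone), goblet cell markers 3 and 2 of 15 and enteroendocrine markers 3 and 0 of 12. Markers of stromal, endothelial and immune cells had 2 and 0 of 15. PRMT1 (log2FC -0.63, SE 0.05, adjusted p = 2.1e-07) and PRMT5 (log2FC -0.81, SE 0.053, adjusted p = 3.8e-08) were both below 0. The Fanconi list had a median of -0.10 and a mean of 0.12 (test up), goblet cell markers -0.30 and -0.078 (up), and NF-kB and inflammatory genes -0.29 and 0.18 (down). The genes that the fixed rule put at the extremes mostly had a group without counts, so their levels are given and no fold. RBBP8NL went from 8.21 ± 0.978 to 25.5 ± 1.13 CPM in WiDr, and PDZK1IP1 from 8.32 ± 0.454 to 46.6 ± 2.91 CPM in WiDr. FSTL1 (22.9 ± 1.36 and 23.1 ± 1.28 CPM) and RNF144A (32.1 ± 1.03 and 28.5 ± 2.04 CPM) had these levels in HCT116 with DMSO and GSK715. GFY went from 16.6 ± 1.42 to 38.6 ± 1.92 CPM in HCT116. RPL17-C18orf32 (a readthrough gene), GTF2H2B (a pseudogene) and BEST1 (121 ± 202 CPM in treated WiDr) are uncertain. Across 16313 genes tested in both lines, which are not independent replicates, the log2 fold changes had r 0.164 and rho 0.183 (r 0.232 over genes of at least 5 CPM). Of 6557 genes called in both, 1827 rose and 2340 fell in each line, where independent calls would give 1380.5 and 1576, and 2390 went opposite ways.

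**Figure D3:**
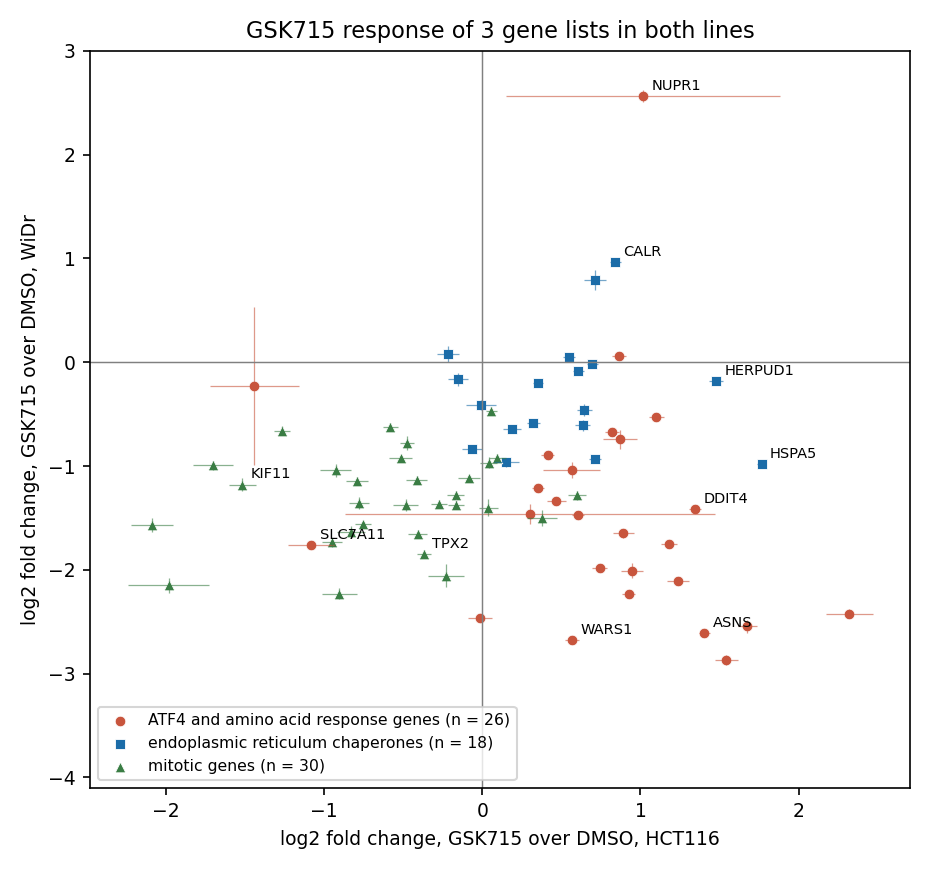
Log2 fold change of GSK715 over DMSO in HCT116 (x axis) and in WiDr (y axis) for the members of 3 gene lists measured in both lines, with SE bars. ASNS stands at 1.40 and -2.61, HSPA5 at 1.77 and -0.98.

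The ONT libraries show the GSK715 response of WiDr on full-length cDNA. The growth factor FGF19 fell 10.9-fold and the immediate early gene EGR1 9.64-fold (n = 2 per group). AREG fell from 196 ± 6.34 to 83.2 ± 7.04 CPM and EREG from 168 ± 0.955 to 71.4 ± 6.65 CPM. SAT1, NUPR1, GDF15 and CDKN1A kept their short-read direction. Of 15877 genes, 1397 passed, 681 higher and 716 lower, 341 and 251 of them at least 2-fold. With DESeq2 277 passed, without DMSO replicate 1 464 and without DMSO replicate 2 591. With library totals 592 were higher and 991 lower.

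Among the largest increases was the vesicle coat gene SEC31B (log2FC 3.07, SE 0.50). Among the largest decreases were FGF19 (log2FC -3.44, SE 0.27), EGR1 (log2FC -3.27, SE 0.17) and LRP11 (log2FC -2.92, SE 0.29). SAT1 (log2FC 1.48, SE 0.093), NUPR1 (log2FC 1.26, SE 0.12) and LASP1NB (log2FC 2.78, SE 0.18) rose, and GDF15 (log2FC -1.50, SE 0.11), CDKN1A (log2FC -1.24, SE 0.22), EREG (log2FC -1.23, SE 0.13) and AREG (log2FC -1.24, SE 0.12) fell. The colonocyte marker PHGR1 rose (log2FC 1.19, SE 0.10), and MUC5AC fell (log2FC -0.95, SE 0.098).

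Of the lists, 7 passed the camera test, and with an estimated correlation the adjusted p was 0.381 for each. Among DNA damage and growth arrest genes, 0 of 27 measured rose, 4 fell and 23 did not pass (median -0.25, camera adjusted p = 0.0003). In the ATF4 and amino acid response list, 1 of 23 measured rose, 8 fell and 14 did not pass (2 and 10 adjusted over the list alone, median -0.24, camera adjusted p = 0.0138), with DDIT3 lower (log2FC -1.18, SE 0.15). Of the endoplasmic reticulum chaperones, 0 of 18 measured rose, 4 fell and 14 did not pass (0 and 6 adjusted over the list alone, median -0.21, camera adjusted p = 0.0025). Of the interferon-stimulated genes, 0 of 33 measured rose, 6 fell and 27 did not pass (median -0.26, camera adjusted p = 0.0111), with IFITM1 lower (log2FC -1.91, SE 0.29). Within MHC class I antigen presentation, 3 of 14 measured rose, 0 fell and 11 did not pass (4 and 0 adjusted over the list alone, median 0.27, camera adjusted p = 0.0114). Of the NF-kB and inflammatory genes, 2 of 17 measured rose, 0 fell and 15 did not pass (median 0.29, camera adjusted p = 0.0404), with NFKBIA higher (log2FC 1.04, SE 0.16). Of the mitochondrially encoded genes, 6 of 13 measured rose, 0 fell and 7 did not pass (7 and 0 adjusted over the list alone, median 0.28, camera adjusted p = 0.00018). Without DMSO replicate 1 the lists of interferon-stimulated genes (adjusted p = 0.0648), ATF4 (0.0519) and NF-kB genes (0.0648) did not pass, nor did the NF-kB list without GSK715 replicate 1 (0.0757).

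The other lists did not pass in the ONT libraries (camera adjusted p from 0.0774 to 0.949), with members that rose and fell as follows. The PRMT family and PRMT5 complex had 1 and 0 of 10 (2 and 3 adjusted over the list alone), methionine and SAM metabolism 2 and 2 of 21 and DNA replication genes 0 and 0 of 31. Mitotic genes had 0 and 3 of 30, homologous recombination and Fanconi genes 0 and 2 of 30 (1 and 2 adjusted over the list alone) and Wnt target and crypt stem cell genes 1 and 2 of 15 (3 and 2 adjusted over the list alone). SR protein and hnRNP splicing factors had 3 and 4 of 33. The snRNP and spliceosome core had 0 and 1 of 29 (0 and 0 adjusted over the list alone), cleavage and polyadenylation factors 0 and 1 of 26 (0 and 0 adjusted over the list alone) and sterol synthesis genes 0 and 2 of 22. Ribosome biogenesis genes had 1 and 1 of 25 and mesenchymal transition genes 1 and 2 of 11 (1 and 3 adjusted over the list alone). Absorptive colonocyte markers had 3 and 4 of 11, goblet cell markers 0 and 2 of 11 (1 and 2 adjusted over the list alone) and enteroendocrine markers 0 and 0 of 1. Markers of stromal, endothelial and immune cells had 1 and 0 of 4 and replication-dependent histone genes 2 and 0 of 14. Signs of median, mean and test differed for methionine and SAM metabolism (-0.012, 0.016, up), Wnt target and crypt stem cell genes (0.13, -0.025, down), goblet cell markers (-0.074, 0.095, down), ribosome biogenesis genes (0.032, -0.019, up) and replication-dependent histone genes (-0.017, 0.073, up).

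The same contrast in ONT and short-read libraries was then compared gene by gene and as an interaction, ONT minus short reads. Across 11602 genes tested in both, which are not independent replicates, r was 0.422 and rho 0.34. Of 894 genes called in both, 298 rose and 484 fell in each, where independent calls would give 135 and 271, and 112 went opposite ways, CEACAM1 among them (1.31 in short reads and -0.96 in ONT). The ONT changes were smaller, with a slope of 0.211 on the short-read ones over genes called in short reads. EREG differed (log2FC 4.74, SE 0.17), as it fell 60.6-fold in the short reads and 2.35-fold in ONT. UNC5B differed likewise (log2FC 5.16, SE 0.70). The difference at SCAMP5 (log2FC -5.71, SE 0.81) was below 0, and IRF2BPL, STS and LINC01088 had a group without counts. The responses differed at 4787 of 24055 genes, 2697 above and 2090 below 0. With library totals the median moved by -0.21, and 1802 were above and 3076 below.

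Most of the mitotic genes differed, as 26 of 30 measured were above 0, 0 below 0 and 4 did not pass (27 and 0 adjusted over the list alone). Their median was 1.26 (camera adjusted p = 7e-25, and 0.0035 with an estimated correlation). In the ATF4 and amino acid response list, 21 of 26 measured were above 0, 1 below 0 and 4 did not pass (23 and 1 adjusted over the list alone). Their median was 1.34 (camera adjusted p = 2.1e-21, and 0.0111 with an estimated correlation), with ASNS at 2.27 (SE 0.11). Of the SR protein and hnRNP splicing factors, 22 of 34 measured were above 0, 0 below 0 and 12 did not pass (25 and 0 adjusted over the list alone). Their median was 0.62 (camera adjusted p = 2e-13, and 0.0255 with an estimated correlation). The remaining 8 calls were lost with an estimated correlation. For ribosome biogenesis genes, 18 of 26 measured were above 0, 0 below 0 and 8 did not pass (19 and 0 adjusted over the list alone). Their median was 0.83 (camera adjusted p = 2.6e-11, but adjusted p = 0.0744 with an estimated correlation). For methionine and SAM metabolism, 8 of 21 measured were above 0, 3 below 0 and 10 did not pass (8 and 5 adjusted over the list alone). Their median was 0.15 (camera adjusted p = 0.012, but adjusted p = 0.0832 with an estimated correlation). For MHC class I antigen presentation, 1 of 15 measured were above 0, 5 below 0 and 9 did not pass (1 and 6 adjusted over the list alone). Their median was -0.43 (camera adjusted p = 0.0031, but adjusted p = 0.153 with an estimated correlation). For interferon-stimulated genes, 9 of 36 measured were above 0, 3 below 0 and 24 did not pass (13 and 4 adjusted over the list alone). Their median was 0.31 (camera adjusted p = 0.0154, but adjusted p = 0.292 with an estimated correlation). Of the recombination and Fanconi genes, 9 of 31 measured were above 0, 1 below 0 and 21 did not pass (9 and 2 adjusted over the list alone). Their median was 0.35 (camera adjusted p = 0.0154, but adjusted p = 0.208 with an estimated correlation). In the snRNP core, 12 of 29 measured were above 0, 2 below 0 and 15 did not pass (15 and 4 adjusted over the list alone). Their median was 0.33 (camera adjusted p = 0.0027, but adjusted p = 0.153 with an estimated correlation). Of the cleavage and polyadenylation factors, 10 of 26 measured were above 0, 0 below 0 and 16 did not pass (11 and 0 adjusted over the list alone). Their median was 0.44 (camera adjusted p = 0.0023, but adjusted p = 0.153 with an estimated correlation). Among sterol synthesis genes, 3 of 24 measured were above 0, 9 below 0 and 12 did not pass (3 and 12 adjusted over the list alone). Their median was -0.56 (camera adjusted p = 0.003, but adjusted p = 0.075 with an estimated correlation), and with members at the floor of counts the median was -0.53. Library totals ended the calls of the methionine (adjusted p = 0.191), interferon (0.117), recombination (0.1) and snRNP lists (0.16). Without DMSO replicate 1 or 2 of the ONT libraries the recombination (0.0616) or the interferon list (0.0577) did not pass either.

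Lists that did not differ between the read types (camera adjusted p from 0.0508 to 0.977) are given as members above and below 0. The PRMT family and PRMT5 complex had 3 and 2 of 12, DNA damage and growth arrest genes 10 and 4 of 29 (12 and 5 adjusted over the list alone) and DNA replication genes 5 and 5 of 32 (6 and 5 adjusted over the list alone). Wnt target and crypt stem cell genes had 4 and 7 of 20 (5 and 7 adjusted over the list alone), endoplasmic reticulum chaperones 5 and 2 of 18 and NF-kB and inflammatory genes 6 and 2 of 25 (8 and 2 adjusted over the list alone). Mesenchymal transition genes had 4 and 4 of 21 (5 and 4 adjusted over the list alone), mitochondrially encoded genes 0 and 2 of 13 (0 and 1 adjusted over the list alone) and replication-dependent histone genes 1 and 0 of 24 (0 and 0 adjusted over the list alone). Absorptive colonocyte markers had 4 and 4 of 19 (5 and 5 adjusted over the list alone), goblet cell markers 3 and 3 of 16 (4 and 5 adjusted over the list alone) and enteroendocrine markers 0 and 1 of 8. Markers of stromal, endothelial and immune cells had 0 and 3 of 13. Signs of median, mean and test differed for goblet cell markers (-0.11, 0.079, down), NF-kB and inflammatory genes (0.36, -0.11, up) and mitochondrially encoded genes (0.08, 0.028, down). PRMT1 (log2FC 0.078, SE 0.10, adjusted p = 0.711) and PRMT5 (log2FC 0.45, SE 0.17, adjusted p = 0.234) did not pass.

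**Figure D4:**
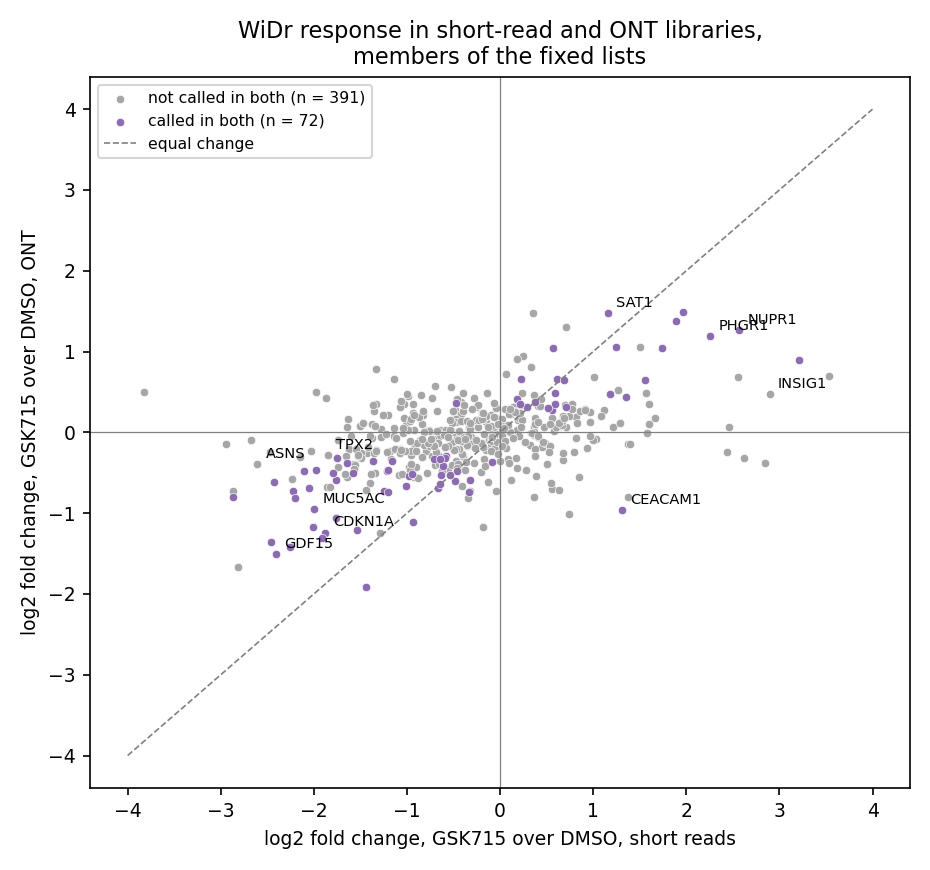
Log2 fold change of GSK715 over DMSO in WiDr for members of the fixed lists in short-read (x axis) and ONT (y axis) libraries, with the line of equal change dashed. SAT1 stands at 1.16 and 1.48, CEACAM1 at 1.31 and -0.96.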

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

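The tests of library scaling and of exchanged labels were chosen only after the results were seen, and the other tests of the 3 patterns were written down before their results. Each pattern was found and tested on the same libraries.

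Pattern 1 is the list of ATF4 and amino acid response genes, which rose in HCT116 and fell in WiDr with GSK715. The tables argue against scaling, since the median difference was -2.52 with TMM, -2.48 with RLE and -2.17 with library totals, and against exchanged labels in a line, since 70.1% of the 645 genes changed at least 2-fold in both lines went the same way (305 down, 147 up and 193 opposite). Among what stays open is the state of the controls: the list stood at a median expression percentile of 97.5 in WiDr with DMSO and 82.1 in HCT116, 15.4 points apart. A candidate explanation is that these genes were already induced in the WiDr controls, by culture conditions or as a line trait. Fresh controls of both lines in the same medium may separate these. The cause stays a hypothesis.

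Pattern 2 is the smaller response of WiDr in the ONT libraries. Short reads thinned to the ONT total keep their fold changes by construction (slope 1.00 on all reads), which cannot test depth. At these 8151 genes the ONT slope was 0.2. Transcript length is argued against as the whole cause. The slope was 0.266 in the shortest of 3 length classes (0.177 and 0.145 in the others). Dilution with untreated RNA predicts like treated shares, and falling and rising genes gave 0.294 and 0.0617. Choosing genes by fold can bias these, so dilution stays open. Depth, separate cultures or handling and count estimation from long reads were not tested and stay open, so the pattern is not called biological.

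Pattern 3 is the excess of genes that fell at least 2-fold in HCT116 under each inhibitor. Low counts are argued against, since 88.9% of such genes of at least 5 CPM fell with GSK025 and 77.3% with GSK715, and so is scaling, where the lowest share was 74.6%. A loss of long transcripts stays open and is a candidate explanation: over genes of at least 5 CPM the fold change fell with exonic length (rho -0.301 for GSK025 and -0.292 for GSK715, against -0.0631 in WiDr, across genes). Of the genes of the shortest, middle and longest class changed at least 2-fold, 55.9%, 89.0% and 96.7% fell with GSK025 and 42.9%, 76.8% and 91.8% with GSK715. Whether RNA quality or an effect of the inhibitors on long transcripts gives this trend was not tested, and RNA integrity was not analysed here.

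Results that differed between the lines by the test of the interaction were 10187 genes and the medians of 8 lists with both correlations: -0.35 for methionine and SAM metabolism, -0.72 for DNA damage and growth arrest genes, -0.88 for mitotic genes, -0.33 for SR protein and hnRNP splicing factors, -2.52 for the ATF4 list, -0.81 for endoplasmic reticulum chaperones, -0.73 for ribosome biogenesis and -0.64 for mesenchymal transition genes. With library totals the methionine (adjusted p = 0.138) and splicing factor lists (0.343) did not pass. Named genes called in opposite directions were CCN2 (2.45 in HCT116, -2.46 in WiDr, difference -4.98), ASNS (1.40 in HCT116, -2.61 in WiDr, difference -4.08), HSPA5 (1.77 in HCT116, -0.98 in WiDr, difference -2.82), CCND1 (0.30 in HCT116, -1.25 in WiDr, difference -1.62), PRMT1 (0.45 in HCT116, -0.12 in WiDr, difference -0.63) and PRMT5 (0.23 in HCT116, -0.51 in WiDr, difference -0.81). With library totals PRMT1 in WiDr (adjusted p = 0.818) and PRMT5 in HCT116 (0.182) did not pass. TAPBP, ATM, MUC12 and CREB3L1 went the other way, as TAPBP (-0.39 in HCT116, 1.08 in WiDr, difference 1.40), ATM (-1.91 in HCT116, 0.82 in WiDr, difference 2.66), MUC12 (-1.24 in HCT116, 2.85 in WiDr, difference 4.02) and CREB3L1 (-0.95 in HCT116, 0.67 in WiDr, difference 1.55). Between ONT and short reads 4787 genes differed, and the medians were 1.26 for mitotic genes, 0.62 for SR protein and hnRNP splicing factors and 1.34 for the ATF4 list.

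Other splits of the samples were counted. For the comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05, and edgeR was the tool run. The real split, 1 of 10 each time, called 8708 genes for GSK025 (highest other 0, with 244 to 329 at an unadjusted p under 0.05), 9157 for GSK715 in HCT116 (0, unadjusted 254 to 343), 8746 between the inhibitors (1, unadjusted 317 to 607) and 12727 in WiDr (0, unadjusted 72 to 98). For the difference between the lines, 1 of 100 splits drawn from 200 called as many genes as the real one, which was itself that one (10187, highest other 5969). Such splits do not separate treatment from handling that the libraries of a group share. The 5969 came from a split that left the WiDr groups whole and mixed those of HCT116, as 7 drawn splits did, and with both lines mixed the highest was 2.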

How the results depend on the processing

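Thinned short reads and the ONT table without IDs from outside Ensembl were chosen after seeing the data. All 7 counts of called genes (in the order GSK025, GSK715 and GSK715 against GSK025 in HCT116, WiDr, ONT, lines and read types) stayed within 1.5 times their main value under RLE, library totals, the replicate block and left-out replicates, with the exceptions below; the block, whose numbers pair no samples, gave 8486, 8881, 8411, 12351, 1706, 9789 and 4384. A test against a 1.5-fold change left 1782, 2375, 2011, 6417, 238, 5205 and 1778, by construction fewer. Thinning left 6601 calls in WiDr, 6396 of them among the main calls. In ONT, no count filter left 251 and DESeq2 277, and the cause was not tested. With a replicate left out the counts ran 7758 to 8787, 8198 to 9240, 7832 to 8473, 11893 to 12409, 464 to 1058, 9534 to 10053 and 3485 to 4775. The lowest of ONT was without DMSO replicate 1, and 591 passed without DMSO replicate 2, where a group rests on 1 library.

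Of 11, 10, 10, 11, 7, 11 and 11 lists called, an estimated correlation kept 4, 7, 5, 3, 0, 8 and 3, and fry called 19, 19, 18, 23, 0, 22 and 15, as it compares no list with other genes. In ONT, where both called 0, 2 and 11 lists had an unadjusted p under 0.05. Library totals left 7 for the read types, and leaving out an ONT replicate 4 to 8 in ONT. The cause was not tested. The correlation between inhibitors was 0.566 and that between lines 0.232 over genes of at least 5 CPM, which drops the noisier genes; with replicates left out they ran 0.345 to 0.487 and 0.127 to 0.173, and 0.345 to 0.418 between read types. Under library totals PRMT1 in WiDr reversed to 0.0071 and no longer passed, and NPM1 between read types reversed to -0.16 and still passed, since that scaling moves all genes by 0.12 and -0.21.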

Other observations

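The gene groups here were chosen after the values were seen, so their counts describe and do not test. MAPK pathway feedback genes, which ERK activity induces, fell in WiDr with GSK715: 0 of 13 rose and 12 fell (median -1.58) in short reads and 0 of 12 rose and 6 fell (median -0.60) in ONT, while in HCT116 7 of 13 rose and 4 fell (median 0.24) with GSK715 and 9 of 13 rose and 2 fell (median 0.35) with GSK025. The phosphatase DUSP6 went down in WiDr (log2FC -1.72, SE 0.036, adjusted p = 1.5e-10) and in its ONT libraries (log2FC -1.39, SE 0.16, adjusted p = 4.9e-09). Small nucleolar RNA host genes went up in HCT116 with GSK715, where 13 of 14 rose and 0 fell (median 0.93), but not with GSK025, where 3 of 14 rose and 4 fell (median -0.014), and 13 of 14 were higher with GSK715 than with GSK025. In WiDr 7 of 14 rose and 5 fell (median 0.24).

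Of the aminoacyl-tRNA synthetases, of which CARS1, SARS1 and WARS1 are also on the ATF4 list, 12 of 18 rose and 3 fell (median 0.31) in HCT116 with GSK715, 1 of 18 rose and 17 fell (median -0.87) in WiDr and 0 of 18 rose and 3 fell (median -0.10) in ONT. GARS1 went to 0.50 in HCT116 and -1.58 in WiDr on the log2 scale, and differed between the lines (log2FC -2.15, SE 0.039, adjusted p = 2e-13). The nuclear long noncoding RNAs MALAT1 and NEAT1 both rose in WiDr with GSK715 (1.56 and 1.40), while in HCT116 MALAT1 fell (-1.52) and NEAT1 rose (0.38); with GSK025 both fell (-2.83 and -2.17).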
